A study of Arabidopsis thaliana with 12 samples.

How the data were processed

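Total RNA of Arabidopsis thaliana was measured in 12 samples, 6 of the wild type (WT, ecotype Columbia 0) and 6 of the psae2 mutant in the same ecotype, which per the labels lacks the photosystem I protein PSI-E2. An array here means the column of values of 1 sample, and whether samples shared a physical array is not known here. The groups and the numbers 1 to 6 within each group come from the sample titles. The tissue, growth conditions, age, array chemistry, hybridisation and image analysis are not given in the sources used here. The values are intensity values on a linear scale as deposited by the authors. How they were background-corrected and scaled is not given in the sources used here. No value lay below 0 or above 100, between 11.9% and 13.7% of the values of an array were exactly 0, and all 12 columns of the table belonged to a sample.

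The table held 3439 probes. The platform annotation listed 1 gene for 692 probes, several genes for 870 and none for 1877. A probe without a listed gene is unnamed here, not without a gene, and no gene was named from a probe with several. Of the 692, 690 matched a gene of the reference table (assembly TAIR10.1), which was used for names and for gene order only. The reference table gives no protein descriptions, so short functional clauses are general background.

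Column medians of the deposited intensity ranged from 0.304 to 0.448, a ratio of 1.48, and column sums had a ratio of 1.21. Because neither was within 5% the columns were treated as not yet on a common scale. Values were set to a floor, the 5th percentile of the positive values of the same array (0.0638 to 0.105), then log2-transformed and quantile-normalized. The rule written before the data were examined spoke of values at or below 0. Positive values under the floor were raised to it as well, which that rule did not state. The 429 probes under the floor on all 12 arrays, 267 of which were 0 on all 12, were left out of the tests, which it did not state either. That left 3010 probes. The 1 gene with 2 probes was averaged, which gave 3009 entries. A further row under the floor on every array of 1 group has only a bound there.

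Differences were tested with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 with Benjamini-Hochberg adjustment and a threshold of 0.05, over all 12 samples and without covariates, as fixed before the data were examined. Figures were drawn with matplotlib 3.10.9. Named genes were the 10 largest increases and the 10 largest decreases among probes of 1 gene with an adjusted p under 0.05, the targeted gene PSAE2 and its paralog PSAE1, and up to 3 members of each gene list tested. Lists were to be tested with camera at a preset correlation of 0.01 where at least 5 members were measured. A member had to have a probe of its own and a reference symbol or synonym that bore its listed name or keyword.

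Whether the sample numbers structure the data was checked on each sample's deviations from its group mean, across probes. Samples with the same number in the other group had correlations of 0.34 to 0.53 in all 6 cases, and among samples of the other group 12 of 12 samples correlated best with that of their own number. The numbers therefore pair the samples, a hint from the data, since the labels do not say what a number marks. Within a group, numbers 1 and 2, 3 and 4, and 5 and 6 correlated at 0.24 to 0.71, against -0.68 to -0.12 for other samples of the group. Deviations from a group mean sum to 0, which pushes the second range down. The standard deviation of log2 differences was 0.27 to 0.39 within these pairs and 0.36 to 0.72 between them. Such numbers were taken as possible technical repeats. Averaging such repeats, which leaves 3 values per group, was an alternative fixed beforehand and is given beside each main result. Which numbers to average was read from these correlations. P-values over 12 samples treat all 12 as independent and measure only the spread between these arrays, which may be technical.

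The procedure was tested on simulated data of 3009 entries with 200 changed for psae2 against WT. With independent errors, 1.99% of the calls of the 12-sample fit were false, and 92% of log2 changes of 1 and 56% of those of 0.5 were recovered. Errors shared within pairs were simulated at a correlation of 0.70, the value estimated from these data. With them, 39.0% of the calls of the 12-sample fit were false, and 31.6% with the replicate number as a block. Averaging pairs brought that to 5.15% and recovered 75% and 17%. With the pair as a random block it was 6.52%, with 89% and 40% recovered. Pairs averaged with the pair as a block recovered 88% of log2 changes of 1 with independent errors and gave 0 calls with errors shared within pairs. Simulated errors were shared only within a group, whereas in the data the same number also correlated across groups. The simulated results with the replicate number, or the averaged pair, as a block may therefore not hold for these data.

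Alternatives fixed beforehand covered the scaling, the treatment of zeros, dim probes, an offset, the replicate number as a block, probes taken alone, the variance model, Welch's test, stricter thresholds, each sample left out and pairs averaged. Added after the data were seen were the blocked fit of averaged pairs, the random block, leaving out each pair of numbers, an offset from positive values, a sign-flip test of the array medians paired by number, and 3 gene sets (the photosynthesis lists pooled, plastid ribosomal proteins matched by locus alone, and a set of NDH complex and thylakoid assembly genes). These sets were tested with camera and with the mixed test of fry in limma, which takes changes in either direction.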

Results

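The arrays measured transcript levels in the WT and in psae2, a mutant without PSI-E2, a peripheral stromal subunit of photosystem I that takes part in docking ferredoxin. There were 6 samples per group, and the comparison asks which transcripts differ in this mutant. Whether the product of the paralog PSAE1 takes the place of PSI-E2 was not tested, so photosystem I may not lack this kind of subunit altogether. Deposited intensities summed to between 2972 and 3610 per array, and the number of arrays limits the precision. Values below are normalized log2 intensities. Because numbers 1 and 2, 3 and 4, and 5 and 6 of a group resembled each other like repeats, means are given over the 3 pair means of a group (SD, n = 3). Adjusted p-values come from limma, over 12 samples and with pairs averaged.

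PSAE2, the targeted gene, and its paralog PSAE1 had 0 probes listed to them each. Their levels were therefore not analysed here, and the labels were not checked against the targeted transcript.

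AT5G52810, which encodes an ornithine cyclodeaminase-like protein known as SARD4 that acts in pipecolic acid synthesis, had the largest decrease among the probes of 1 gene. It fell by 1.82 on the log2 scale, 3.52-fold, from 0.99 ± 0.11 in the WT to -0.83 ± 0.17 in psae2 (SD, n = 3; adjusted p = 4.43e-07 over 12 samples and 0.016 with pairs averaged). CUTA, a copper-binding protein of the chloroplast, fell by 1.52, from 1.08 ± 0.37 to -0.44 ± 0.28 (SD, n = 3; adjusted p = 6.19e-05 and 0.0405). AT3G52070 fell 2.14-fold, from 1.89 ± 0.18 to 0.79 ± 0.33 (SD, n = 3; adjusted p = 0.000125 and 0.0455). In the opposite direction, AT2G21530, which encodes a protein with a forkhead-associated domain, rose by 1.37, from -2.33 ± 0.36 to -0.96 ± 0.23 (SD, n = 3; adjusted p = 0.000175 and 0.0405). AT1G78620, known as VTE6 and a kinase of phytyl phosphate in tocopherol synthesis, rose by 0.91, from -0.31 ± 0.16 to 0.59 ± 0.24 (SD, n = 3; adjusted p = 0.000289 and 0.0455).

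The other increases that passed with pairs averaged were those of AT1G07040 (log2 difference 1.18), AT5G39410 (0.80), AT4G09970 (0.80) and AT5G19900 (0.79). AT4G09970, like AT2G38950, was under the floor in 3 of 6 WT samples, and AT1G07040 and AT5G19900 were in 1 of 6 each. AT2G06040 was under the floor in all 6 WT samples and in 0 of 6 psae2 samples. Its log2 difference of 1.07 is therefore taken against the floor (adjusted p = 0.000132 and 0.0208). The floor also sets the spread of its WT values to 0, so these p-values may be too small. Its log2 difference was 1.046 with each array centred on its median and 0.95 without psae2 sample 4. With values at 0 set to missing it was 2.001 (adjusted p = 0.0113). That setting also drops the floor for small positive values. AT2G06040 was at 0 in only 2 of 6 WT samples, so the change is not one of zeros alone. In the same setting the log2 difference of AT2G38950, which had 0 zeros in either group, was 1.67. With an offset in place of the floor the log2 difference of AT5G19900 was 0.52. Among the other named increases it was also smaller for AT4G09970 (0.54), AT1G07040 (0.80), AT2G21530 (1.08) and AT1G08845 (0.60), for example. It was larger for AT2G06040 (1.15) and for APTX (1.88, against 1.38 with the floor). APTX, an aprataxin-like protein, was listed at 0 in all 6 WT samples and at 0.0747 to 0.518 in psae2, with a mean deposited intensity of 0.267. Its adjusted p was 0.0224 over 12 samples and 0.142 with pairs averaged. The floor sets the spread of its WT values to 0 too, so the same limit applies to these p-values. AT2G38950, which encodes a jumonji-domain protein (2.15-fold higher), and AT1G08845 (log2 difference 0.82) also passed over 12 samples and not with pairs averaged, with adjusted p of 0.168 and 0.163. In AT1G08845, WT sample 2 lay apart from the other WT samples, and AT2G38950 lost its call over 12 samples when any 1 of 6 samples was left out (adjusted p 0.0511 to 0.0525). APTX, AT2G38950 and AT1G08845 each lost the call with numbers 3 and 4, or 5 and 6, left out of both groups.

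Of the 10 largest decreases, 3 passed with pairs averaged and the other 7 did not. The latter were AT5G66090 (log2 difference -1.01), AT1G01250 (-0.89), the drought-induced gene DI21 (-0.86), AT5G35100 (-0.83), AT4G15840 (-0.80), the cyanase gene CYN (-0.79) and AT3G51500 (-0.72). Their adjusted p with pairs averaged ran from 0.0743 for AT4G15840 to 0.273 for AT1G01250. With the pair of each group as a random block, AT5G66090, AT4G15840 and CYN passed (adjusted p 0.0242, 0.0107 and 0.0267). Among the decreases, the differences of AT5G66090, AT1G01250, AT5G35100, AT3G51500, DI21 and AT3G52070 varied by over 2 times between pairs. That of AT1G01250 was -0.27, -0.57 and -1.84 in the respective pairs. With numbers 5 and 6 left out of both groups, the difference was -0.41 for AT1G01250 (adjusted p = 0.0448 in limma), -0.47 for AT5G35100 (0.104) and -0.46 for AT3G51500 (0.163). With numbers 3 and 4 left out AT5G66090, AT1G01250, DI21, AT5G35100 and CYN lost the call, as did DI21 with numbers 1 and 2 left out (-0.60, adjusted p = 0.0793). The calls of AT1G01250 and AT5G35100 over 12 samples were lost when any 1 of 7 and any 1 of 9 samples, respectively, was left out, and with the values as deposited (adjusted p 0.0667 and 0.112). All 20 named genes had the same direction in 3 of 3 pairs of numbers. They were picked on these same samples for large differences, so this is close to given and adds no support.

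Of the 10 genes that passed with pairs averaged, AT5G52810, CUTA, AT2G21530 and AT5G39410 also passed with the random block and with pairs averaged and the pair as a block. AT1G07040, AT4G09970 and AT2G06040 did not pass with the random block (adjusted p 0.104, 0.0774 and 0.0502). AT1G78620, AT5G19900 and AT3G52070 did not pass with pairs averaged and the pair as a block (0.0553, 0.0553 and 0.0763).

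**Figure D1:**
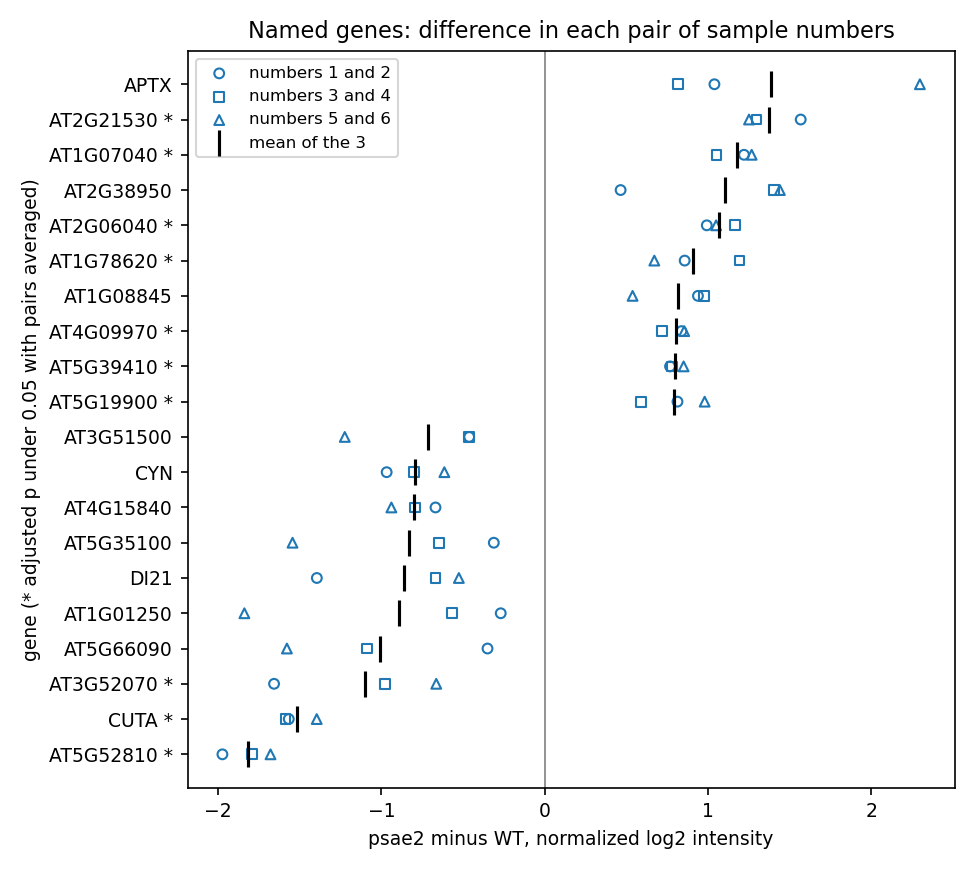
Difference between psae2 and WT for the 20 named genes, in normalized log2 intensity on the x axis, with 1 open symbol per pair of sample numbers and a black bar for the mean of the 3. Stars mark the 10 genes with an adjusted p under 0.05 in limma with pairs averaged. AT5G52810 lies at -1.97, -1.79 and -1.68, and AT1G01250 spreads from -0.27 to -1.84.

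Among probes without a single listed gene, probe 2119 was listed at 0 in 4 of 6 WT samples and above the floor in all 6 psae2 samples. Its log2 difference of 2.38 therefore rests mostly on the floor value in the WT (adjusted p with pairs averaged 0.0208). Probe 251, which lists 2 genes, rose by 1.36, from -0.47 ± 0.32 to 0.89 ± 0.05 (SD, n = 3; adjusted p with pairs averaged 0.0333). Probes 3453 and 1701 fell by 1.86 and 1.83, with adjusted p with pairs averaged of 0.0374 and 0.0405. Probe 1701 was under the floor in 3 of 6 psae2 samples, so its difference rests in part on the floor value. These 4 probes were picked by the size of the fitted difference, floor values included, among those that passed both fits.

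In all, 671 of 3009 entries passed the threshold in limma over 12 samples, 358 higher and 313 lower in psae2. With pairs averaged, 79 passed, 37 higher and 42 lower, and all 79 were among the 671. Among the 602 probes of 1 gene the counts were 131 (72 higher, 59 lower) and 14 (9 higher, 5 lower). With the replicate number as a block over 12 samples, 1010 passed. With pairs averaged and the pair as a block 44 passed, and with the pair of each group as a random block 181 did. In the 12-sample fit without a block, the direction of the calls depended on scaling. Of them, 53.4% were higher in psae2 after quantile normalization, 84.0% with the values as deposited and 40.9% with each array centred on its median. As deposited, the median log2 value of the arrays was higher by 0.18 in psae2 (two-sided exact permutation p = 0.0476 over 12 arrays and 0.3 over the 6 pair means, where 0.1 is the smallest possible). These regroupings ignore the numbers. The psae2 median was the higher at 6 of 6 numbers, by 0.15 to 0.21. Flipping signs within numbers, a test added after the data were seen, gave a two-sided exact permutation p of 0.0312, and within the 3 pairs of numbers one of 0.25, each the smallest possible. The directions given here are therefore relative to that common shift.

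**Figure D2:**
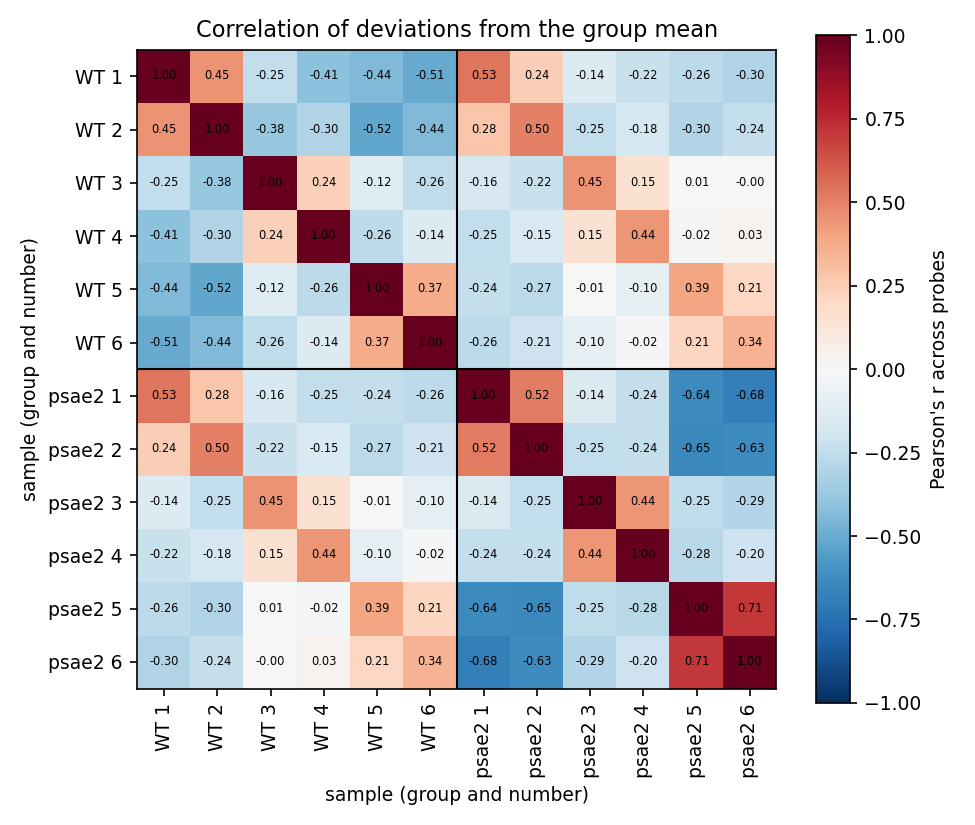
Pearson's correlation, across probes, of the deviations of each sample from its group mean, for the 12 samples named by group and number on both axes. Samples of the same group in the same pair of numbers reach 0.24 to 0.71, and samples of the same number in different groups 0.34 to 0.53.

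Few genes of photosynthesis were named in the probe annotation. Of the 350 loci in the 21 lists fixed beforehand, 17 had a probe of their own, and 10 of these also bore the listed name. The longest list had 3 tested members, so 0 lists reached the 5 members needed for a test. In 13 of the 21 lists, 0 members had a probe of their own, among them those for photosystem I antenna, electron transport, senescence and defence, heterotrophic plastid and roots, and flower and seed.

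Pooled after the data were seen, the photosynthesis lists held 8 tested genes, of which 1 passed over 12 samples. This was PRK, phosphoribulokinase of the Calvin cycle, with a log2 difference of 0.32 and an adjusted p of 0.0412. With pairs averaged its adjusted p was 0.317, it was higher in 2 of 3 pairs, its call was lost without WT sample 1, 2, 3 or 4 or psae2 sample 3, 4 or 6 (adjusted p 0.0614 to 0.087), and adjusted over the list alone 0 of the 8 passed. The photosystem I subunit gene PSAN had a level of 2.11 ± 0.24 in the WT and 2.12 ± 0.25 in psae2 (SD, n = 3), a log2 difference of 0.01 that turned to -0.13 with each array centred on its median. The photosystem II genes PSBW, PSBY and PSB27 had differences of -0.17, 0.19 and -0.17, and the antenna gene LHB1B2 one of -0.18. With each array centred on its median these were -0.32, 0.09, -0.27 and -0.28, and as deposited -0.11, 0.30, -0.063 and -0.076, in the same order. The chlorophyll synthesis genes CHLM and AT1G74470 (CHLP) had differences of 0.12 and 0.06, the latter -0.10 with each array centred on its median and the former 0.30 as deposited. PRK had 0.20 when centred and 0.41 as deposited, and its call was also lost with numbers 1 and 2, or 3 and 4, left out. PSB27 changed sign without psae2 sample 2 or 6, and CHLM with numbers 5 and 6 left out. None of these 7 passed over 12 samples in limma, though PSBW did with trend and robust eBayes (adjusted p = 0.034). With the replicate number as a block, LHB1B2 and PSBW passed (adjusted p = 0.0407 and 0.046) and PRK did not (0.0534). With pairs averaged and the pair as a block neither LHB1B2 nor PSBW passed (0.282 and 0.322). With each array centred on its median PSBW passed over 12 samples (0.041) and PRK did not (0.215). The pooled list as a whole had a camera p of 0.853 with the preset correlation and p = 0.872 with an estimated correlation, where 0.853 and 0.872 were also the adjusted values over the 3 sets added. Camera tests for a shift in 1 direction, and these genes went in both directions. The mixed test of fry, which takes changes in either direction, gave an unadjusted p of 0.0165 over 12 samples and 0.499 with pairs averaged. Of the plastid ribosomal proteins, matched by locus alone, 0 of 5 passed in limma over 12 samples, and 0 of 5 adjusted over the list alone.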

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

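Dixon's ratio was taken in 60 sets of 6 samples, for the 20 named genes, 8 pooled photosynthesis genes and 3 measures of the arrays. Each group was a set of its own, sets without spread were left out, and other genes discussed were not checked. In 3 sets, 1 sample was set apart from the others by more than the limit of that ratio. Chance alone gives about 1 in 20, which is 3 of 60. AT1G08845 was at -3.34 in WT sample 2 and at -2.57 to -2.17 in the other WT samples (ratio 0.654). AT5G52810 was at 0.76 in WT sample 4 and at 0.97 to 1.08 in the others (ratio 0.643). AT1G74470 was at 2.01 in WT sample 1 and at 1.57 to 1.67 in the others (ratio 0.776). No biological explanation was tested for these values.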

How the results depend on the processing

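Leaving out a pair of numbers, averaged pairs with a block, the random block and the offset from positive values were chosen after seeing the data. The 671 calls became 1010 with the replicate number as a block, 79 with pairs averaged, 44 with pairs averaged and the pair as a block (34 shared by both averaged fits), 181 with the pair as a random block, 284 with numbers 3 and 4 left out of both groups (669 without 1 and 2, 516 without 5 and 6), 306 at an adjusted p under 0.01 and 231 with at least 1.5-fold. A stricter threshold lowers a count by construction; beyond that and the test of pairings, the cause was not tested. With 1 sample left out the count was 552 to 668. Of the 20 named genes, 10 passed with pairs averaged, 7 with the pair as a block too, 10 with the random block and 12 with numbers 3 and 4 left out; with 1 sample left out 17 to 20 passed. None of the 20 changed direction in the 24 to 26 alternatives that gave it a value. The blocks, averaged pairs and the variance model leave the log2 difference as it is in this balanced design. The genes were also picked for large differences on these samples, so this adds little support. Calls were lost with 1 sample left out for AT1G01250 (any WT sample or psae2 sample 5; adjusted p 0.0523 to 0.0699), AT2G38950 (WT sample 1, 3 or 5 or psae2 sample 4, 5 or 6; 0.0511 to 0.0525), and AT5G35100 (WT sample 1, 2, 3, 4 or 6 or psae2 sample 3, 4, 5 or 6; 0.0523 to 0.0703).
The median log2 difference over all entries was 0.0128 after quantile normalization, which fixes it near 0 and makes its permutation test void. It was 0.173 as deposited, -0.0343 with median centring and 0.0360 with zeros missing and no floor. The cause was not tested beyond the scaling itself. With 1 sample left out it was 0.00562 to 0.0216. Of the 8 pooled photosynthesis genes, 1 passed; 2 did with the replicate block and with trend and robust eBayes, 0 with pairs averaged, with the pair as a block, with the random block and with numbers 1 and 2 or 3 and 4 left out, and 0 to 1 with 1 sample left out. PSAN (log2 difference 0.01) was -0.13 with median centring and -0.053 to 0.0728 with 1 sample left out. AT1G74470 was -0.10 with median centring and -0.048 without numbers 3 and 4, CHLM -0.0876 without numbers 5 and 6, and PSB27 -0.42 to 0.0225 with 1 sample left out; none of these passed in these settings, and the cause was not tested. Beyond PRK, LHB1B2 and PSBW the replicate block changed no named gene's call. PSAE2 and the gene lists have no value to recompute. The offset fixed beforehand, the 5th percentile of all values, was 0 and was not run; with 0.0798, that of the positive values, 666 entries passed. Dim signal limits genes with samples under the floor.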

Other observations

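A set of 12 genes of the NDH complex, which carries electrons around photosystem I, and of thylakoid complex assembly was chosen after the values were seen. Of these, 9 were tested and 5 passed over 12 samples in limma, while 0 passed with pairs averaged. Adjusted over the list alone, 5 passed over 12 samples and 1 with pairs averaged. NdhS, a subunit of the complex, had a log2 difference of -0.28 and CRR21, an editing factor for it, one of -0.40. PIFI (0.41), Cpn60beta4, a chaperonin subunit (0.64), and AT1G22700, known as PYG7 and needed for photosystem I assembly (0.66), were higher in psae2. All 5 had the same direction in 3 of 3 pairs of numbers. Their adjusted p with pairs averaged ran from 0.0743 for AT1G22700 to 0.312 for NdhS. The set as a whole had a camera p of 0.518 with the preset correlation and p = 0.534 with an estimated correlation (0.853 and 0.872 adjusted over the 3 sets added), and its members went in both directions. A set picked on these samples is no independent evidence.

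A group of 5 probes was listed at 0 in all 6 WT samples and above 0 in all 6 psae2 samples, and 0 probes showed the reverse. They were that of APTX and the unnamed probes 1801, 2278, 3655 and 4100, with mean deposited intensities in psae2 of 0.267, 0.178, 0.0975, 0.0771 and 0.119. Of the 6 psae2 values, 1, 1, 3, 4 and 1 lay under the floor of their array, in the same order. Zeros were fewer on the psae2 arrays in general, at 11.9% to 12.8% of probes against 13.0% to 13.7% in the WT.

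The tests on added background, on a single scale factor and on linkage were chosen after the result was seen. The 12-sample count of 671 entries was matched by 1 of 100 splits of the 12 samples, the real one, and the highest of the others gave 151. Chance can be excluded for that count only if the 12 samples are independent. Because the numbers pair the samples, the 32 splits that part all 6 numbers were run too, and the highest of the others gave 1. Most of these splits break the pairs 1 and 2, 3 and 4, and 5 and 6. Splits that keep the pairs number 10, with 671 for the real one and 151 for the highest of the others, too few for a share under 0.05. With pairs averaged the real split gave 79 and the highest of the other 9 of 10 splits gave 0, and the same limit applies.

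The drop from 671 to 79 calls was set against other ways to pair the numbers, which also leave 3 values per group. The 14 other ways to pair the 6 numbers gave 184 to 744 calls, with a median of 617. Of them, 0 gave as few calls as the pairing of 1 with 2, 3 with 4 and 5 with 6, and 0 gave up to 1.5 times as many. If pairs share errors, the other pairings part members of a pair into different means. That makes those means alike and can raise the count. They therefore do not show what 3 independent values per group would give, and an effect of fewer samples alone cannot be excluded. Numbers 1 and 2, 3 and 4, 5 and 6 being repeats that share errors is a candidate explanation. The pairing was itself read from the correlations of the same data, so the test is not independent of it, and the labels leave open whether the repeats are technical.

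The higher deposited values in psae2 held in each pair of numbers, at 0.21, 0.17 and 0.17 on the log2 scale. Under a scale factor per column, dim and bright probes would shift alike. Probes at 0 on any array were left out here, so the dimmest probes were not covered. The rest were parted by mean brightness into 4 equal parts of 717 or 718 probes. The shift of the dimmest part exceeded that of the brightest by 0.14 on average. In the respective pairs it did so by 0.32, 0.11 and -0.0021. The mean lay within the spread between pairs, the limit set for a single scale factor. For numbers 1 and 2, however, the shift fell from 0.33 in the dimmest part to 0.015 in the brightest, which a single factor would not give. The spread is wide because the pairs differ, so the test cannot decide. Under an added background, the linear difference would be alike in dim and bright probes. Brightest over dimmest it had a median ratio of 2.68, with 0.36, 2.68 and 7.42 in the pairs, which decides nothing. A true difference in total transcript between the groups was not tested.

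A segment around the mutated gene that came from another genotype could give calls near PSAE2. Within 500 genes of the locus, 4 of 17 tested single-gene entries passed over 12 samples (23.5%), against 127 of 583 elsewhere (21.8%; two-sided Fisher's exact p = 0.773). With pairs averaged it was 1 of 17 against 13 of 583 (two-sided Fisher's exact p = 0.334). The 4 were AT2G21720, AT2G23890, AT2G21530 and AT2G19280. With 17 entries such a segment cannot be told apart from an even spread of calls.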
